A study of Bos taurus with 6 samples.

How the data were processed

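Muscle RNA of 6 cattle was sequenced, 3 of the Angus breed and 3 of the Luxi breed, all 18 months old. Per the labels' protocols, the tissue was frozen on dry ice, RNA was extracted with Trizol, and sequencing libraries were made from 1 microgram of total RNA by Illumina's standard procedure for a HiSeq2000. The labels name tissue and breed but neither the muscle nor the sex of the animals. The aligner, the gene set, the counting rule for reads that match several genes, strandedness and the authors' statistical test are not given in the sources used here.

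The analysis used 1 deposited table, which holds the 232 genes that passed the authors' filter for the comparison of the breeds. Genes below that filter were not analysed here. For each gene the authors deposited a count per breed, which is the mean of the raw read counts of 3 libraries, since every value was a whole multiple of 1/3. They also deposited an RPKM per breed, in which reads are scaled to gene length and library depth, per the file headers, and its values are those of a mean over 3 libraries. Where the count was 0, the authors deposited an RPKM of 0.001 in its place. The deposited log2 ratio was that of the RPKM values of Luxi over Angus. The p-value and FDR of each gene are those the authors deposited for this comparison, per the file headers. The largest deposited FDR was 9.67e-04 and the smallest absolute log2 ratio was 1.00. No column of values per sample was left unused, and the breed columns are printed as the authors' means.

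Gene names came from the authors' deposited table. Of 163 entries with a gene identifier, 148 matched the RefSeq gene table of assembly GCF_002263795.3 (ARS-UCD2.0), which was used for names alone, and 12 of these have another symbol there. The remaining 69 entries were clusters of expressed sequence tags (ESTs), and 4 of them had a deposited protein match that the gene table could name. No genome build is named in the sources used here, so no coordinates are given.

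Reads per library were worked back from the breed means. The mean count gives the whole number of reads summed over 3 libraries, and the mean RPKM, printed to 6 significant digits, weights the reads of each library by the depth of that library. A search over depths found those for which every gene had a whole-number solution. In each breed 1 set of depths remained. It gave at least 1 solution for each of 210 Angus and 207 Luxi genes with reads, and 81 and 55 of these genes had a single solution. The reads of 57 genes were thus known in all 6 libraries. For the other genes the range over all solutions was carried forward, and a statement was made only where every solution shared it. The reads of the middle library are the least well fixed by this method, so a gene carried by a middle library is named less often than it occurs. On 6 simulated tables with 1251 genes in all, the search found depths within 10 reads of the true ones for 6 of 6 tables, the true reads were among the solutions for 1251 genes, and 512 of 512 single solutions were the true reads.

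The recovered depth was 5736365, 5577223 and 5429317 reads in the Angus libraries and 6047227, 5890554 and 5799075 reads in the Luxi libraries, each to within 4 reads. Libraries are called the deepest, middle and shallowest of their breed, and which animal gave which library is not given in the sources used here. Intervals and limits from reads cover counting error alone, since reads without molecular identifiers are not independent molecules.

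The authors' p-value was examined by recomputing it. A test of 2 Poisson counts (Audic and Claverie), run on the breed mean counts truncated to whole numbers as if each breed were 1 library of the mean depth, and doubled, came within 5% of the deposited p for 121 of 130 genes with a deposited p above 1e-10, 79 of 79 higher in Angus and 42 of 51 higher in Luxi. Of the smaller p-values above 0, the recomputed p was over 1000 times smaller for 15 of 25 genes higher in Luxi and 0 of 67 higher in Angus. Calls without a library rest on the recomputed p, which thus matches the authors' test less closely for genes higher in Luxi. With the reads summed over the 3 libraries it did so for 0 of 130. The spread between animals did not enter such a test. Among genes higher in Luxi, 9 had a deposited p of exactly 0, and the smallest above 0 was 4.44e-16, near the limit of floating-point arithmetic, against 1.01e-235 among genes higher in Angus, so the smallest p-values of the 2 directions are not comparable.

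The design, the alternatives, 20 gene lists and the rule for named genes were fixed before the data were examined. The share of genes higher in Angus was tested against equal shares by an exact two-sided binomial test, with an exact Clopper-Pearson interval at 95%. The level of the genes of each direction was compared by a two-sided permutation test of the difference in median log2 mean RPKM with 100000 resamples. For each list with at least 4 listed genes, a Fisher's exact test of direction was planned. Genes are named in the text when they belong to the 12 largest absolute log2 ratios of a direction (with a gene symbol, above 0 in both breeds and at least 1 RPKM in the higher breed), to the 4 highest values of a direction, or to the up to 4 largest absolute log2 ratios of a gene list. This rule gave 51 genes, of which 1 is not reported here. Genes named outside it are described as chosen after their values were seen.

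The alternatives fixed beforehand were an FDR of at most 1e-04, an absolute log2 ratio of at least 2, at least 1 RPKM in the higher breed, leaving out genes at 0 in 1 breed, the value of the higher breed as the level, and 1 RPKM added to both values. Those chosen after seeing the data were leaving out each library in turn with the recovered reads, keeping only genes whose libraries separate by breed, leaving out genes with over 2/3 of the depth-adjusted reads of the higher breed in 1 library, leaving out EST clusters and adding EST clusters with a protein match to the lists. A gene was kept without a library when its RPKM ratio stayed at or above 2 and its recomputed p stayed at or below the largest deposited p of 3.86e-05. That limit is the deposited p of KRT19, so a gene with a deposited p near it can lose its call with little change in its ratio. For genes listed at 0 in 1 breed the ratio was taken against the deposited 0.001 RPKM, so in practice only the p could end their call. Fold changes are ratios of the deposited RPKM values, and none is given against a breed listed at 0. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.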

Results

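RNA sequencing measured gene expression in muscle of Angus cattle, a beef breed of Scottish origin, and Luxi cattle, a yellow cattle breed of China. Muscle was taken from 3 Angus and 3 Luxi animals at 18 months of age. Recovered depths were 5429317 to 5736365 reads per Angus library and 5799075 to 6047227 reads per Luxi library. The deposited values are breed means for 232 genes that the authors listed as different between the breeds, and they carry no SD. Reads per library were recovered from those means for part of the genes.

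The comparison asks which genes differ in expression between the muscle of Angus and of Luxi cattle. Among genes with a symbol and above 0 in both breeds, 2 myosin heavy chain genes had the largest ratios. In the authors' deposited table, MYH4 (gene identifier 408020), the heavy chain of the fastest limb muscle fibres, averaged 28.3 RPKM in Angus and 1.00 RPKM in Luxi, 28.2-fold higher in Angus. The Angus library with most MYH4 reads held 33.7% to 96.7% of them, so its dependence on 1 library was not determined. MYH13 (gene identifier 511687), a superfast myosin of eye muscles, averaged 17.6 and 0.601 RPKM in the authors' deposited table, 29.3-fold higher in Angus, but 98.5% to 99.1% of its Angus reads came from the deepest Angus library. On the Luxi side, the imprinted noncoding RNA H19 averaged 481 RPKM in Luxi and 205 RPKM in Angus, and SLC16A6, a transporter of the monocarboxylate family, 82.4 and 13.8 RPKM, in the authors' deposited table.

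Of the 232 listed genes, 147 were higher in Angus and 85 in Luxi. The Angus share of 63.4% (exact 95% interval 56.8% to 69.6%) differed from equal shares (exact two-sided binomial p = 5.65e-05), a statement about the list, since genes are not independent replicates. Equal shares also assume a filter alike for both directions, but the deposited p matched the recomputed p less closely for genes higher in Luxi. Whether this changed the share could not be tested, since genes below the filter were not analysed. Without the deepest or the middle Angus library, the share among genes sure to pass no longer differed from equal shares, at 54.7% (exact p = 0.309) and 54.3% (exact p = 0.379). Among the genes that can pass it still did, at 59.0% (exact p = 0.0159) and 64.4% (exact p = 2.95e-05). Leaving out a library can only remove listed genes, and genes listed through high values in that library can lose their call. A fall in the Angus share without an Angus library can thus come in part from how the genes were listed. Without the middle Angus library, 70 genes higher in Angus were sure to pass and 139 can pass, so that lower share comes largely from genes whose call was not determined. Without the middle Luxi library the share was 77.4% of the 106 genes sure to pass and 63.8% of the 221 that can pass. Among genes above 0 in both breeds, 122 were higher in Angus with a median ratio of 2.67-fold and a largest of 31.6-fold, and 63 were higher in Luxi with a median of 2.62-fold and a largest of 6.86-fold. The other 47 genes were listed at 0 in 1 breed, 25 of them in Luxi and 22 in Angus. Median expression was 8.98 RPKM for genes higher in Angus and 8.26 RPKM for genes higher in Luxi, a log2 difference of 0.12 that the permutation test did not separate from 0 (p = 0.772).

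**Figure D1:**
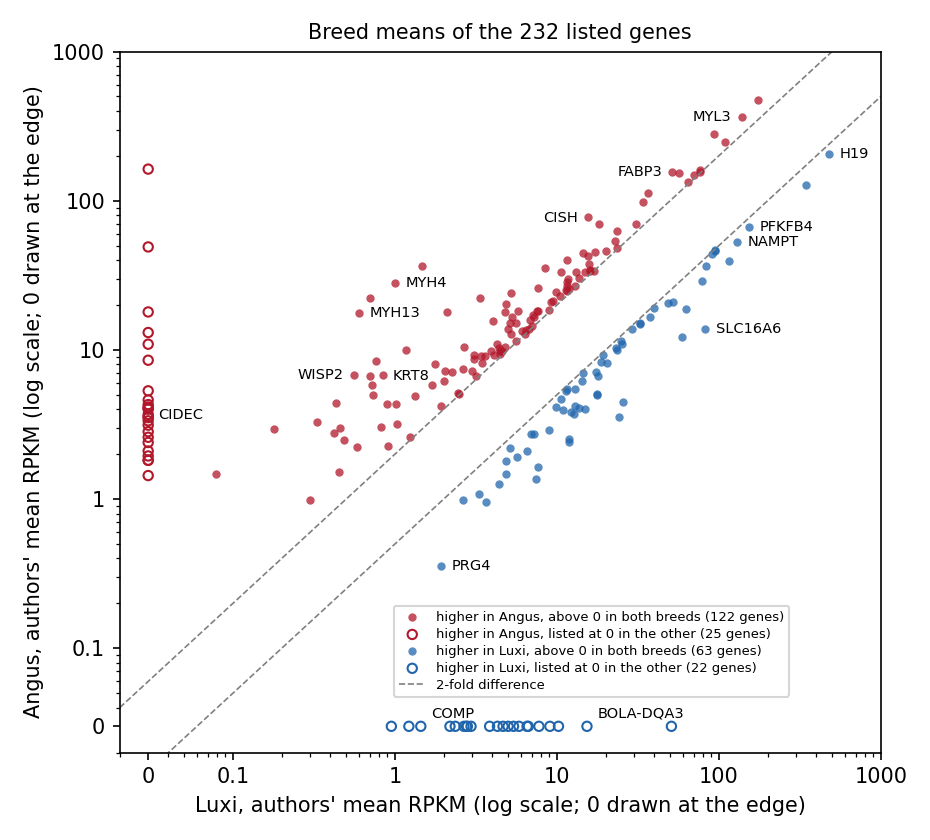
Each point is 1 of the 232 listed genes, with the authors' mean RPKM in Luxi on the x axis and in Angus on the y axis (both log scales), red for genes higher in Angus and blue for genes higher in Luxi. Dashed lines mark a 2-fold difference, open circles at the edges are the 25 and 22 genes listed at 0 in 1 breed, and MYH4 and MYH13 lie farthest from the Angus line among labelled genes above 0 in both breeds.

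Several of the largest ratios in favour of Angus kept their call whichever library was left out. KRT8, a keratin of simple epithelia, was 8.04-fold higher in Angus, HIST1H2AA (now H2AC6), a core histone, 8.52-fold, and PCBD1, an enzyme of tetrahydrobiopterin recycling, 9.54-fold, from the RPKM values of the authors' deposited table. L1CAM, an adhesion molecule of neurons and Schwann cells, was 5.16-fold higher at 2.51 against 0.486 RPKM in the authors' deposited table. These 4 genes kept their ratio of at least 2 and their call whichever of the 6 libraries was left out. The shallowest Angus library held 59.4% to 60.2% of the Angus reads of HIST1H2AA, whose log2 ratio was 2.35 to 2.38 without it, against 3.09 in full. CISH, an inhibitor of cytokine receptor signalling, averaged 77.2 RPKM in Angus and 15.6 RPKM in Luxi in the authors' deposited table and also kept its call, but 1 Angus library can hold up to 72.3% of its Angus reads. Without the shallowest Angus library its log2 ratio lay between 1.04 and 2.03, against 2.31 in full, and its separation between the breeds was not determined. In KRT8 the Angus libraries held 106, 86 and 23 reads and the Luxi libraries 6, 15 and 7, from deepest to shallowest.

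Some other large Angus ratios came mainly from 1 library, and others lost their call, or had none determined, without 1 library. IL17RB, a cytokine receptor, was 16.3-fold higher in Angus in the authors' deposited table, with 101, 3 and 7 reads in the deepest, middle and shallowest Angus libraries and 7 reads in Luxi. WISP2 (now CCN5), a secreted matrix protein, was 12.3-fold higher with 275, 18 and 16 reads, and TPSB1, a mast cell tryptase, 10.05-fold higher with 51, 4 and 12 reads. All Angus libraries of WISP2 and TPSB1 lay above all their Luxi libraries, and those of IL17RB did not. Without the deepest Angus library the log2 ratios of Angus over Luxi of IL17RB, WISP2 and TPSB1 were 1.20, 1.07 and 1.90. These ratios stayed above 2-fold, but the recomputed p did not pass, so none kept its call. TPSB1 also lost its call without the middle Luxi library (2.97). For MYH13 the sign turned without the deepest Angus library, to a log2 ratio between -1.34 and -0.58. MYH4 stayed higher in Angus whichever library was left out, with a log2 ratio of at least 0.49 over all solutions. That lowest value was without the middle Angus library, which can hold up to 96.7% of the Angus reads of MYH4, so its call without that library and its separation between the breeds were not determined. SKAP1, an adaptor protein of T cells, and TMEM98 were 6.52-fold and 6.57-fold higher in Angus in the authors' deposited table. Their Angus libraries all exceeded their Luxi libraries, but neither kept its call without the deepest Angus library, where the log2 ratios were 1.85 and 2.60. Both ratios stayed above 2-fold, and the authors' deposited p of 3.08e-05 for SKAP1 and 2.63e-05 for TMEM98 were already near the limit of 3.86e-05. TMEM98 also lost its call without the middle Angus library (2.35) and without the deepest Luxi library (2.41).

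The largest ratios in favour of Luxi were smaller than those in favour of Angus. After SLC16A6 at 5.98-fold, ARSG, a lysosomal sulfatase, was 4.63-fold higher in Luxi, SLC27A6, a fatty acid transporter, 3.80-fold, SULT1A1, which sulfates phenols, 3.17-fold, and PON3, a lactonase, 3.04-fold, from the RPKM values of the authors' deposited table. ACTC1, the actin of heart and developing muscle, was 3.47-fold higher, TMEM52 3.71-fold, ART3 3.29-fold and GABPB2, a subunit of a transcription factor of mitochondrial genes, 3.12-fold, from the same columns of the authors' deposited table. Without the middle Luxi library the log2 ratio of Angus over Luxi lay between -2.18 and 2.09 for PON3, between -2.41 and 0.68 for TMEM52 and between -2.24 and 0.34 for SULT1A1, so neither call nor direction was determined there. SLC16A6, SLC27A6, ART3 and GABPB2 stayed higher in Luxi without it, and ARSG without the shallowest Luxi library, but their calls were not determined. Some of the Luxi ratios came mainly from 1 library. PRG4 (lubricin, 5.39-fold higher in Luxi) had 148, 6 and 10 reads in the deepest, middle and shallowest Luxi libraries, PTX3 (a secreted pattern recognition protein, 3.26-fold) 148, 6 and 8, and HABP2 (a hyaluronan-binding protease, 3.05-fold) 153, 7 and 13. Without the deepest Luxi library these 3 genes were higher in Angus, with log2 ratios of 0.30, 1.20 and 0.87. That library also held 70.0% to 81.0% of the Luxi reads of ACTC1, whose log2 ratio without it lay between -0.64 and 0.02.

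The highest mean values included those of muscle structure and energy genes. In the authors' deposited table, an EST cluster with a protein match to FHL1, a LIM domain protein of the sarcomere, averaged 475 RPKM in Angus and 174 in Luxi, and MYL3, the myosin light chain of slow fibres and heart, 365 and 139. A pair of EST clusters with no named protein followed at 282 and 248 RPKM in Angus, against 93.7 and 109 in Luxi, in the authors' deposited table. After H19, the highest values in Luxi were those of LOC100337233, annotated as similar to a Z-disc immunoglobulin-domain protein, at 344 RPKM against 128 in Angus, in the authors' deposited table. PFKFB4, a regulator of glycolytic flux, averaged 154 RPKM in Luxi and 66.3 in Angus, and NAMPT, which makes the NAD precursor nicotinamide mononucleotide, 130 and 53.3, in the authors' deposited table. The reads of these abundant genes had many solutions, so how evenly the animals of a breed contributed was not determined. Without the middle library of the higher breed none of their calls was determined, and the direction was determined for MYL3 and PFKFB4 alone, that of PFKFB4 not without the shallowest Luxi library (log2 ratio -1.27 to 0.17).

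Of the 20 gene lists, 14 held at least 1 listed gene, and 17 of 23 listed members were higher in Angus. No list reached the 4 listed genes that the test of direction needed, so the lists are described without a test. Slow fibre proteins had MYL3 (2.62-fold) and fast fibre proteins MYH4, both higher in Angus in the authors' deposited table. Without the middle Angus library the log2 ratio of MYL3 lay between 0.10 and 1.98. Sarcomere proteins shared by fibre types split, with embryonic myosin MYH3 2.74-fold higher in Angus and ACTC1 higher in Luxi, in the authors' deposited table, and the log2 ratio of MYH3 lay between 0.34 and 1.31 without the shallowest Angus library and between 2.89 and 3.42 without the deepest Luxi library, against 1.46 in full. Fatty acid oxidation had FABP3, which carries fatty acids within muscle cells, at 155 RPKM in Angus against 51.6 in Luxi, and ACADL, which oxidises long-chain acyl-CoA, 2.22-fold higher in Angus, in the authors' deposited table. The middle Angus library left both open, with log2 ratios without it between -0.07 and 2.17 for FABP3 and between -0.01 and 1.55 for ACADL. Oxidative phosphorylation had the complex I subunits NDUFB4 and NDUFA3, 2.41-fold and 2.16-fold higher in Angus in the authors' deposited table. NDUFB4 lost its call without the deepest Luxi library (log2 ratio 0.70 to 0.92) and had no determined direction without the middle Angus library (-0.58 to 1.34). NDUFA3 lost its call without the shallowest Angus library but stayed higher in Angus (0.14 to 0.94). Glycolysis and glycogen metabolism had HK2, the hexokinase of muscle, 2.21-fold higher in Luxi in the authors' deposited table, with no determined direction without the middle Luxi library (log2 ratio -1.73 to 0.60) or the shallowest (-1.41 to 0.02).

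Lists for fat, nerve, epithelium and connective tissue also had members. Adipocyte genes were higher in Angus in the authors' deposited table, the adipokine ADIPOQ at 15.1 against 5.14 RPKM and the lipid droplet protein CIDEC at 3.69 RPKM against a listing at 0. The deepest Angus library held 64.3% to 81.1% of the Angus reads of ADIPOQ and 61.5% of those of CIDEC, and without it the log2 ratio of ADIPOQ lay between -0.26 and 0.66. CIDEC kept its call whichever library was left out, which for a gene listed at 0 rests on the p alone. Nerve and Schwann cell genes included NCAM1, a neural cell adhesion molecule, 2.10-fold higher in Angus in the authors' deposited table, with a log2 ratio between -0.09 and 1.48 without the middle Angus library. Epithelial genes had KRT8 and KRT19, the latter 3.69-fold higher in Angus in the authors' deposited table, with 51, 61 and 4 reads in the deepest, middle and shallowest Angus libraries and 8, 20 and 5 in the Luxi libraries. KRT19 lost its call without the deepest or the middle Angus library (log2 ratios 1.65 and 1.37). It also lost it without the deepest or the shallowest Luxi library (1.69 and 1.54), against 1.88 in full. Its ratio stayed above 2-fold each time, and its deposited p was itself the limit of 3.86e-05, so any rise in p ended the call. Extracellular matrix genes split: COL6A5 (listed as LOC785805), a collagen chain, was 18.8-fold higher in Angus with 94.3% to 95.2% of its Angus reads in the deepest Angus library, and COMP, a matrix protein of cartilage and tendon, averaged 1.45 RPKM in Luxi against a listing at 0, in the authors' deposited table, with 51 of its 64 Luxi reads in the deepest Luxi library.

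Growth and response lists were also mixed. Myogenic and growth genes had IGFBP5, which binds insulin-like growth factors, 2.74-fold higher in Angus, NCAM1, and the growth arrest gene GADD45A, 2.26-fold higher in Luxi, in the authors' deposited table. Without the deepest Angus library the log2 ratio of Angus over Luxi of IGFBP5 lay between -0.57 and 0.37, and without the shallowest Luxi library that of GADD45A lay between -0.94 and 0.45. Immediate early genes had the nuclear receptor NR4A2, 2.71-fold higher in Angus, and the transcription factor CEBPD, 2.01-fold higher in Luxi, in the authors' deposited table. The direction of NR4A2 was not determined without the middle Angus library (log2 ratio -1.45 to 2.01), nor that of CEBPD without the middle Luxi library (-1.59 to 0.83), and the call of CEBPD was not determined whichever library was left out. The circadian list had NFIL3, a repressor of clock output genes, 2.38-fold higher in Angus (log2 ratio 0.01 to 1.70 without the middle Angus library), and the immune cell list had BOLA-DQA3, an antigen-presenting chain, at 15.3 RPKM in Luxi against a listing at 0 in Angus, in the authors' deposited table. The lists fixed for ribosomal proteins, proteolysis and atrophy, interferon-induced genes, red blood cells, heat shock proteins and endothelium held 0 of the listed genes. Outside the fixed lists, and picked after the values were seen, IFI47, an interferon-induced GTPase, averaged 6.55 RPKM in Luxi against a listing at 0, and IFITM1, an interferon-induced membrane protein, 2.40 RPKM in Angus against a listing at 0, in the authors' deposited table. Genes annotated as similar to ribosomal proteins went both ways in the authors' deposited table, LOC782855 3.34-fold higher in Luxi, LOC613970 24.9-fold higher in Angus and LOC100299317 at 49.0 RPKM in Angus against a listing at 0. The HSP90-like genes LOC783577 and LOC781339 averaged 4.05 and 3.56 RPKM in Angus against listings at 0 in the authors' deposited table.

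Across the list, it was not determined for most genes whether the libraries of the breeds overlap. Over 2/3 of the reads of the higher breed came from 1 library in 34 genes and did not in 66, with 132 not determined. Of these 34 genes, 25 were higher in Angus, 18 of them carried by the deepest Angus library, and 9 were higher in Luxi, 7 of them carried by the deepest Luxi library. All libraries of the higher breed lay above all libraries of the other in 63 genes and did not in 30, with 139 not determined. Of the 63, 43 were listed at 0 in 1 breed, where reads in every library of the other are enough. These 43, and the calls kept by genes listed at 0, take a listed 0 as 0 reads in each library. Where processing set a breed to 0 instead, neither is shown. The 20 above 0 in both breeds were 19 higher in Angus and 1 higher in Luxi. Among genes above 0 in both breeds, separation failed in 23 of 122 higher in Angus and 7 of 63 higher in Luxi. It was not determined in 80 and 55 of them, so the 2 directions cannot be compared by the 19 and 1. Among the 27 genes above 0 in both breeds whose reads were known in all 6 libraries, 13 separated completely. The share of 10% for genes without a difference holds for unselected genes only, and these were listed for their ratios. With 3 animals against 3, no exact permutation test of a single gene can give a two-sided p under 0.10. The call was kept whichever library was left out in 36 genes, 24 higher in Angus, 14 of them listed at 0 in Luxi, and 12 higher in Luxi, 11 of them listed at 0 in Angus. For genes listed at 0 only the p could end the call, and of the 185 genes above 0 in both breeds 11 kept it. The call was lost without at least 1 library in 102 of the 232 genes and was not determined in 94.

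**Figure D2:**
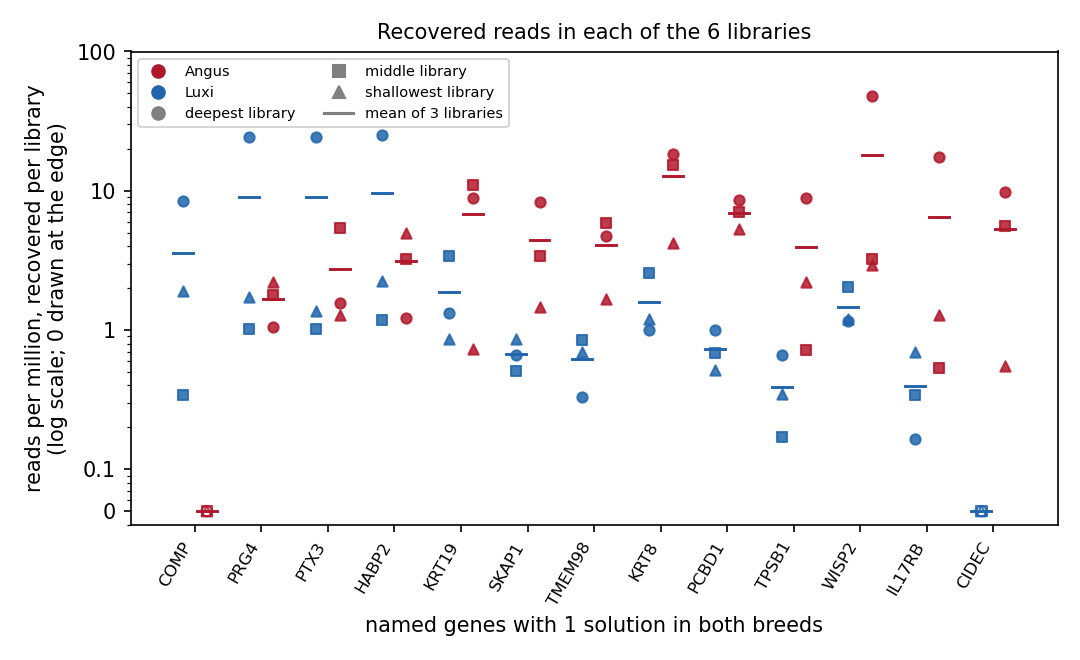
Reads scaled to library depth in each of the 6 libraries (y axis, log scale) for the 13 named genes with a single solution in both breeds (x axis), red for Angus and blue for Luxi, with symbols for the depth order and a bar for the mean of 3 libraries. PRG4, PTX3 and HABP2 are carried by the deepest Luxi library and WISP2 and IL17RB by the deepest Angus library. All Angus libraries of KRT8, PCBD1, WISP2, TPSB1, SKAP1 and TMEM98 lie above all Luxi libraries, and those of IL17RB and KRT19 do not.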

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

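Alternatives that leave out libraries, EST clusters or genes carried by 1 library, that keep only genes whose libraries separate by breed, or that add EST clusters to the lists were chosen after seeing the data, and the others before. The 232 listed genes were reduced to 83 at an absolute log2 ratio of at least 2 and to 63 when all libraries of the higher breed had to lie above all of the other, in both cases because the condition itself removes genes. Leaving out libraries from the recovered reads gave 36 to 221 genes, the lower end being those sure to pass whichever library is left out and the upper end those that can pass without the middle Luxi library. The share higher in Angus lay between 61.6% and 65.9% and kept its side of the threshold under all alternatives that keep 6 libraries. Without a library it ranged from 54.3% to 77.4%, the latter over genes sure to pass without the middle Luxi library, against 63.8% over those that can pass. Among genes sure to pass it lost the threshold without the deepest Angus library (54.7%, exact p = 0.309), without the middle Angus library (54.3%, exact p = 0.379) and over the genes that pass whichever library is left out (66.7%, exact p = 0.0652). Among genes that can pass it was 59.0% (exact p = 0.0159) and 64.4% (exact p = 2.95e-05) without those 2 libraries.

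The log2 difference in level between genes higher in Angus and in Luxi, 0.12 in the full list, had no stable sign: -0.15 at an absolute log2 ratio of at least 2, -0.14 without genes at 0 in 1 breed, -0.22 without EST clusters, -0.22 among genes whose libraries separate by breed, and -0.33 to 0.55 without a library, with -0.20 among genes sure to pass without the middle Angus library. No alternative separated it from 0 (permutation p from 0.193 to 1.00), and the cause of the sign changes was not tested. Adding 1 RPKM to both breed means left 32 of 51 ratios of named genes within the limit set for no change, moved 19 and reversed 0. No gene list reached 4 listed genes in any of the 6 alternatives run for the lists. The binomial alternative for the lists, the other normalization and the pseudocounts planned for columns of values per library were not run, since no list was large enough and the table holds breed means. No paired analysis was possible, since the labels describe no link between an Angus and a Luxi animal and the recovered libraries could not be assigned to animals.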

Other observations

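All tests in this part, and the genes it names beyond those of the report, were chosen after the results were seen. Beside the tryptase TPSB1, the mast cell carboxypeptidase CPA3 was 4.83-fold higher in Angus and the receptor KIT 3.87-fold, from the RPKM values of the authors' deposited table. The deepest Angus library held 75.2% of the Angus reads of TPSB1, 63.6% of those of CPA3 and 76.8% to 77.3% of those of KIT. PMP2, a myelin protein of peripheral nerve, was 4.24-fold higher in Angus beside L1CAM in the authors' deposited table. HIST1H2BD, a core histone, was 2.30-fold higher and an EST cluster with a histone protein match 10.99-fold higher in Angus beside HIST1H2AA, in the authors' deposited table. The shallowest Angus library held 78.8% of the Angus reads of that cluster, and its libraries did not separate by breed. Nuclear-encoded NDUFB4 and NDUFA3 were joined by 3 EST clusters with protein matches to mitochondrially encoded NADH dehydrogenase and cytochrome c oxidase subunits, 2.89-fold, 2.20-fold and 2.10-fold higher in Angus in the authors' deposited table.

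Beside SULT1A1, the SULT1C-like gene LOC509792 was 3.05-fold higher in Luxi, and SULT1C4 averaged 2.67 RPKM in Luxi against a listing at 0 in Angus, in the authors' deposited table, with 47 of the 61 SULT1C4 reads in the middle Luxi library. The lactate transporter SLC16A3 was 2.24-fold higher in Luxi and PRKAG3, a muscle AMP-activated kinase subunit, 2.14-fold, in the authors' deposited table. The glucose transporter SLC2A3 averaged 18.2 RPKM in Angus and 5.78 in Luxi in the authors' deposited table, with 69.2% to 83.0% of its Angus reads in the deepest Angus library. FBP1, an enzyme of gluconeogenesis, was also higher in Angus, with 67, 1 and 4 reads in the deepest, middle and shallowest Angus libraries and a listing at 0 in Luxi. Class I antigen-presentation sequences went both ways: 1 EST cluster had 90 reads in Luxi and 0 in Angus, another had 255 reads in Angus and 41 in Luxi, and a last one had 110 in Angus and 0 in Luxi. An EST cluster of an endogenous retroviral polymerase gene had 89.1% to 89.6% of its Angus reads in the deepest Angus library, and 1 with an envelope protein match had 88.9% to 89.9% in the shallowest.

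The first pattern is the 34 genes with over 2/3 of the depth-adjusted reads of the higher breed in 1 library. Depth alone gives 1 library at most 34.3% of the unadjusted reads of a breed. The shares that picked these genes were already adjusted for depth, so this value is no test of depth. Of the 27 of these genes above 0 in both breeds, 18 are sure to have a library of the higher breed at or below a library of the other, but only 3 of them (PTX3, HABP2 and an EST cluster) by more than counting error (binomial test, Bonferroni-corrected p below 0.05). On this bound a difference between the breeds in every sampled animal stays open for the set, but the bound was changed after these values were seen, and the first one, any overlap in most of the genes, would argue against it. The deepest Angus library held at least 61.5% of the Angus reads of both adipocyte genes listed. These were ADIPOQ at 15.1 RPKM and CIDEC at 3.69 RPKM in Angus in the authors' deposited table. Neither is shown to belong to the 34 genes, since CIDEC stayed under 2/3 and ADIPOQ was not determined (64.3% to 81.1%). CIDEC, listed at 0 in Luxi, also kept its call whichever library was left out. Whether fat cells in that sample contributed cannot be told from these 2 genes, nor apart from other differences between animals. The piece of tissue taken and the animals themselves stay open, untested.

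The second pattern is the 47 genes listed at 0 in 1 breed with 45 or more reads in the other, among them GLO1 (468 reads in Angus) and EST clusters with protein matches to myosin-7 (3592 reads in Angus) and PFKM (734 reads in Luxi). A candidate explanation is a processing step that set a breed to 0, or dropped the gene, unless all 3 libraries held reads: 0 of 136 gene and breed pairs with a single solution had a library at 0, where 7.55 were expected from the spread between libraries, a model-based probability of 7.2e-05, although with counting error alone 1.37 were expected and the probability was 0.118. Near-identical copies that share reads may also play a part. EST clusters and LOC genes made up 26 of these 47 genes (55.3%) and 67 of the other 185 (36.2%, two-sided Fisher's exact p = 0.01998). They were classed by name and no sequences were compared, so this is no direct test of copies. These tests exclude neither one another nor a breed difference in sequence or expression, which was not tested.

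The third pattern is MYH13, 29.3-fold higher in Angus in the authors' deposited table, with 12, 31 and 19 reads in the deepest, middle and shallowest Luxi libraries and at most 22 and 15 in the middle and shallowest Angus libraries. The deepest Angus library can hold at most 49.3% of the Angus reads of MYH4 but holds at least 98.5% of those of MYH13. This argues only against MYH4 reads assigned to MYH13 at a like rate in every library. Misassignment in 1 library alone, or of reads from other myosin genes, was not tested and stays open. The breed difference of MYH13 is that of 1 library, and what set that animal or its sample apart was not tested.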
